A study of Homo sapiens with 60 samples.

How the data were processed

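RNA was sequenced from A549 cells (a human non-small cell lung carcinoma line, batch A) grown in RPMI with 10% serum and treated for 24 h with vehicle, wortmannin at 10 µM or 1 of 6 hot-water plant extracts at 500, 100 or 20 µg/mL. Per the labels the RNA had an integrity number above 7 and the directional libraries were read in pairs of 100 bp on an MGI instrument. The sample labels give the vehicle as 0.1% DMSO and the series text as 2% DMSO; the disagreement was not resolved here, and the labels do not state the solvent of the extract samples. The series text adds that an extract with an IC20 below 500 µg/mL was given at its IC20 and dilutions of it; the doses printed are those of the sample labels. A second kind of extract that the series text names was not analysed here.

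The authors trimmed reads with Trim Galore 0.6.5 after FastQC 0.11.9, aligned them to GRCh38 with STAR 2.7.3a and estimated expression with RSEM 1.3.3; the annotation release is not stated. The deposited values are expected counts per gene (expected_counts) that the authors made with RSEM and did not normalize. Of the values 9.07% were not whole numbers, which is how RSEM shares reads between genes with similar sequence. The table held 60675 gene IDs in 270 columns, of which the 60 columns that match the samples were used. Gene symbols were assigned to the IDs of the table from a separate name list, or else from GENCODE release 29. Positions came from GENCODE release 29 on GRCh38. Among the list genes, 538 of 539 were matched to an ID.

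Expected counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 20 groups, which left 16986 tested and 43689 not tested. Libraries were scaled by TMM factors, between 0.949 and 1.038. All 60 libraries entered a single quasi-likelihood fit with robust dispersion and 40 residual degrees of freedom. Each contrast had a two-sided quasi-likelihood F test, adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. A called gene passed that threshold. The SE of a log2 change was calculated as its absolute value divided by the square root of the F statistic. It is thus not a separate estimate from the fit. The 28 contrasts were wortmannin and each extract and dose against vehicle, 500 against 20 µg/mL of each extract, and 3 pairs of extracts at 500 µg/mL. Interaction contrasts tested whether the 500 against 20 µg/mL change differed between the extracts of a pair. The sample codes fall into sets: Poria with Atractylodis, Glycyrrhizae with Panax, and Angelicae with Paeoniae, with vehicle and wortmannin outside them. Comparisons with vehicle therefore crossed sets, and the labels do not say whether a set is a batch.

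Totals of 19073735 to 28753478 reads per library put 9359 genes at a mean of at least 10 CPM, and the median biological coefficient of variation was 4.78%. Reads without molecular identifiers are not independent molecules, so this precision covers the spread between these libraries only. In counts simulated at this depth 50 genes were changed at each size. The test recovered 26 genes changed 1.25-fold, 35 changed 1.5-fold, 43 changed 2-fold and 47 changed 4-fold. It made 3 false calls, and called 0 genes in a group without changes. Genes were drawn independently, so the simulation lacks differences that many genes of a library share. Its false calls may be too few for the real libraries, where a split across the groups called up to 94 genes (Atractylodis, 500 and 20 µg/mL).

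A total of 27 gene lists were written before the data were examined. They cover FOXO, cholesterol, fatty acid, NRF2, aryl hydrocarbon receptor, ATF4, unfolded protein, heat shock, p53, G1/S, G2/M, hypoxia, NF-kB, interferon, glucocorticoid, metallothionein, lysosome, MAPK feedback, TGF-beta and ribosome biogenesis genes, alveolar markers, ribosomal proteins, mitochondrial mRNAs, histones, and markers of blood, fibroblast or endothelial cells and hepatocytes. Lists with at least 4 tested members were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a contrast, which is the list adjusted p. The test was repeated with a correlation estimated from the data, and with fry, which asks only whether a list's genes move on balance 1 way. A p given after a list's count is the preset one unless stated. Counts described as adjusted over the list alone had p adjusted over the members of that list only. They are not comparable with calls adjusted over all genes tested. Genes were named by a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls (5 and 5 between doses or extracts) among called genes with a symbol, at least 1 CPM in 1 of the groups, and all 3 treated libraries beyond all 3 control libraries. It added the 2 called members of each list with the smallest p. Exceptions are stated where they occur.

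The alternatives tried for each count and each named gene were RLE size factors, no filter on low counts, DESeq2 1.42.0, a fit on the 6 compared libraries only, the replicate number as a block over all groups or within each set, and leaving out each library in turn. A left-out library leaves 2 in its group. A named gene that DESeq2 left without an adjusted p, as genes of low mean can be, was counted as not called. Such a gene was not shown to fail the DESeq2 test. Offsets per library for GC content and gene length, available for 99.28% of tested genes, were added after the data were seen, as was a fit without the 6 libraries that stood apart on the second principal component. The replicate numbers were checked for pairing by correlating residuals of equal numbers between the compared groups. All 10 splits of the 6 libraries of each contrast were refitted. Figures were drawn with matplotlib.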

Results

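Messenger RNA was measured by RNA sequencing in A549, a human non-small cell lung carcinoma line, 24 h after treatment. The 60 libraries fall into 20 groups of 3: a DMSO vehicle, the PI3K inhibitor wortmannin at 10 µM as positive control, and 6 hot-water plant extracts at 500, 100 and 20 µg/mL. The extracts are Poria Cocos, Atractylodis Rhizoma, Glycyrrhizae Radix (liquorice root), Panax Ginseng, Angelicae Gigantis Radix and Paeoniae Radix (peony root), named below by their first word. Each library held between 19073735 and 28753478 gene-assigned reads. Levels are given as normalised read counts (CPM, the count in a library scaled to 1e6 reads), mean ± SD over n = 3 libraries, and changes as log2 fold changes from edgeR with Benjamini-Hochberg adjusted p over 16986 genes. The vehicle level is the background for every change against vehicle. On the second principal component 6 libraries stood apart: vehicle replicate 1, replicate 1 of Glycyrrhizae at all 3 doses, and Poria replicate 2 and Atractylodis replicate 1 at 500 µg/mL. Without all 6, the counts of called genes against vehicle were 7410 for wortmannin. At 500 µg/mL they were 315 for Poria, 95 for Atractylodis, 1121 for Glycyrrhizae, 65 for Panax, 16 for Angelicae and 1275 for Paeoniae. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries only.

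Wortmannin addressed whether the system records a known inhibitor. It lowered the genes of cell division and raised FOXO-activated genes, which PI3K signalling is known to hold down. TOP2A, the topoisomerase that untangles replicated DNA (ENSG00000131747, GRCh38 chromosome 17, 40388516 to 40417950), fell by 2.81 on the log2 scale, from 262 ± 11.8 to 37.3 ± 0.163 CPM (n = 3, adjusted p = 9e-53). The mitotic kinesin KIF20A fell by 3.58, from 61.9 ± 1.34 to 5.18 ± 0.657 CPM, and the mitotic kinase PLK1 fell by 3.23. IGFBP1, an insulin-repressed binding protein that FOXO factors activate (ENSG00000146678, chromosome 7, 45888357 to 45893668), rose by 5.04 ± 0.318 (SE), from 0.121 ± 0.0729 to 4.08 ± 0.609 CPM (adjusted p = 3.17e-21). GPX3, a secreted glutathione peroxidase, rose from 47.8 ± 1.72 to 303 ± 14.7 CPM (adjusted p = 4.27e-44).

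Of 22 FOXO-activated genes 17 rose with wortmannin and 1 fell, among them TXNIP at 1.94 and ERBB3 at 0.71 (list adjusted p = 2e-05). All 25 G2/M genes fell with a median of -2.81 (9.1e-237), as did all 26 DNA replication and G1/S genes with a median of -1.36 (7.6e-72), where RRM2, a ribonucleotide reductase subunit, fell by 1.97. Of 30 ATF4 and amino acid response genes 19 fell and 2 rose (4e-07); PHGDH, which opens serine synthesis, fell by 2.08. Of 21 unfolded protein response genes 13 fell and 3 rose (4e-07), with the chaperone CALR lower by a log2 change of -0.98. Of 12 fatty acid synthesis genes 10 fell and 1 rose, and FADS2, a fatty acid desaturase, fell by 0.87 (4.6e-05). These 6 lists kept their calls with an estimated correlation between genes.

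A further set of lists moved with wortmannin under the preset correlation only. Heat shock genes had 11 of 17 members lower, HSP90AA1 by a log2 change of -0.82 (list adjusted p = 0.00094, but adjusted p = 0.17 with an estimated correlation). Interferon-stimulated genes had 18 of 23 members higher, but the antiviral gene MX1 stood at 14.1 ± 8.35 CPM against 1.53 ± 0.232 in vehicle, a wide spread (list adjusted p = 0.00047, but adjusted p = 0.23 with an estimated correlation). Lysosome genes had 17 of 30 higher and 5 lower, with the protease CTSB at 0.90 (9.5e-05, but adjusted p = 0.15 with an estimated correlation). Ribosome biogenesis genes had 16 of 22 lower, NOLC1 at -0.47 (9.3e-05, but adjusted p = 0.15 with an estimated correlation), and cytosolic ribosomal proteins had 28 of 30 higher, RPL4 at 0.31 (1.1e-05, but adjusted p = 0.2 with an estimated correlation).

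The other lists were not called with wortmannin by either form of the test, although members changed. Among 27 NRF2 targets 8 rose and 12 fell, and among 25 cholesterol genes 3 rose and 8 fell. Among 25 NF-kB and cytokine genes 11 rose and 6 fell, and SOD2, a mitochondrial superoxide dismutase, rose by 1.23. Among 24 hypoxia and glycolysis genes 5 rose and 13 fell, CA9 by a log2 change of -1.25. Rises and falls were 13 and 5 of 22 p53 targets, 4 and 1 of 6 aryl hydrocarbon receptor targets, 9 and 3 of 23 immediate early and MAPK feedback genes, and 6 and 8 of 21 TGF-beta and matrix genes. Among 13 glucocorticoid receptor targets 5 rose and 6 fell; their median was -0.16 and their mean 0.15. Rises numbered 2 of 5 metallothionein genes, 2 of 9 alveolar and airway markers (ABCA3, a surfactant lipid transporter, by 1.41) and 4 of 6 histone genes, whose near-identical copies share reads. Among 13 mitochondrially encoded mRNAs 2 fell. Of the markers of other cell types, 1 of 4 blood genes rose (CD68), 1 of 5 fibroblast and endothelial genes rose and 1 fell (DCN and COL3A1), and 2 of 5 hepatocyte genes rose and 1 fell.

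In total 4065 genes rose and 4056 fell with wortmannin (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), which is 47.81% of the genes tested; 460 rose and 510 fell at least 2-fold.

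The extracts were tested against vehicle to ask which genes each of them changed. At 500 µg/mL the called genes, rises and falls, were 420 and 284 with Poria, 61 and 20 with Atractylodis, 758 and 958 with Glycyrrhizae, 77 and 28 with Panax, 15 and 18 with Angelicae, and 872 and 768 with Paeoniae. Most of these changes were small: at least 2-fold rises and falls numbered 4 and 3, 8 and 1, 23 and 34, 1 and 0, 0 and 0, and 17 and 15 in that order.

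**Figure D1:**
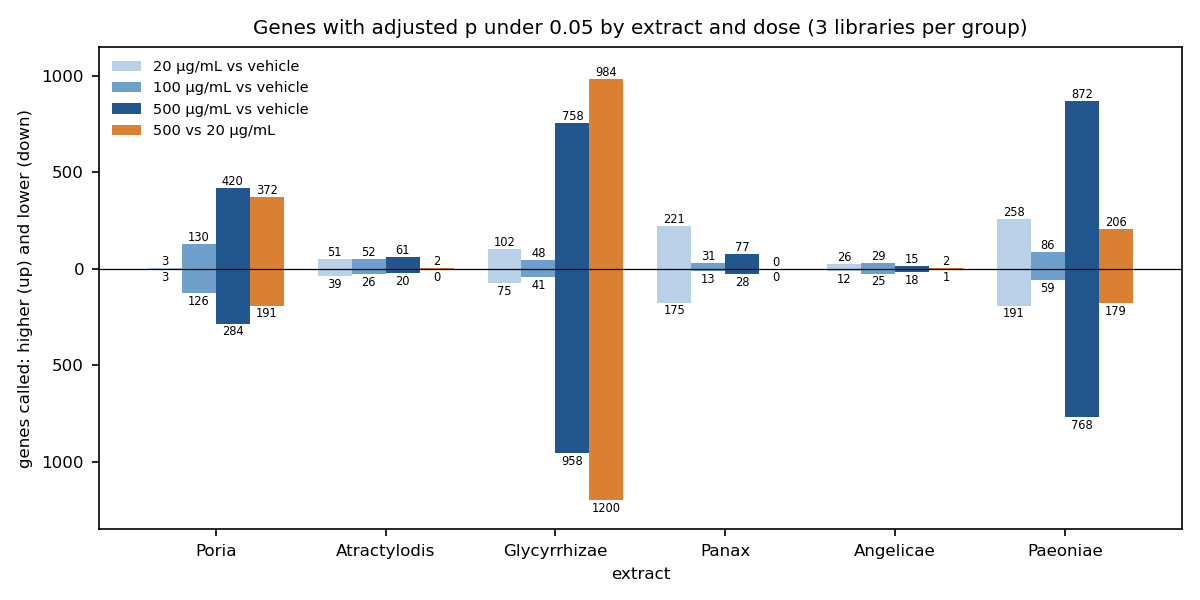
Bars give the number of genes called higher (above 0) and lower (below 0) against vehicle for each extract at 500, 100 and 20 µg/mL, 3 libraries per group. A further bar per extract compares 500 with 20 µg/mL without the vehicle, and is tallest for Glycyrrhizae (984 and 1200). Glycyrrhizae (758 and 958) and Paeoniae (872 and 768) stand out at 500 µg/mL, while Panax has more calls at 20 µg/mL (221 and 175) than at 500 µg/mL (77 and 28).

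Poria at 500 µg/mL raised genes of cell division and some NRF2, ATF4 and heat shock genes by small steps. HMOX1, the haem-degrading NRF2 target (ENSG00000100292, chromosome 22, 35380361 to 35394214), rose from 53.9 ± 4.35 to 80.3 ± 7.64 CPM (n = 3), a log2 change of 0.58 ± 0.089 (SE, adjusted p = 2.85e-05). TOP2A rose from 262 ± 11.8 to 333 ± 7.07 CPM, by 0.35 (3.68e-09), and CDC20, an activator of mitotic exit, also by 0.35. ID2, an inhibitor of helix-loop-helix factors that BMP signalling induces (ENSG00000115738, chromosome 2, 8678845 to 8684453), fell by 0.75 ± 0.075, from 26.6 ± 2.11 to 15.9 ± 0.531 CPM (5.97e-10). The small heat shock protein gene CRYAB fell by 0.62, and ANGPTL4, a lipoprotein lipase inhibitor, rose by 0.50.

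With Poria at 500 µg/mL 21 of 25 G2/M genes rose (median 0.28, list adjusted p = 1.4e-52, or 1.8e-12 with an estimated correlation) and 21 of 26 G1/S genes rose (median 0.20, 6.3e-29), MCM4 and RRM1 by 0.22 and 0.23. Of 30 ATF4 genes 10 rose and 1 fell (5.3e-08), with STC2 at 0.38, and 6 of 27 NRF2 targets rose (8.2e-10), with TRIM16L at 0.31 and ME1 at 0.26. Of 12 fatty acid genes 4 rose (2e-06), with FADS1 at 0.30. Of 17 heat shock genes 4 rose, or 11 adjusted over the list alone (3.3e-08); HSP90AA1 rose by 0.22. Of 23 MAPK feedback genes 4 rose (3e-05), with the growth factor EREG at 0.41. The FOXO list moved down (median -0.13, 7.5e-05) with 1 of 22 members higher and 1 lower. These calls held with an estimated correlation; those for cholesterol (3 of 25 higher, adjusted p = 0.15 with an estimated correlation), hypoxia (3 of 24 higher, 0.13) and ribosome biogenesis (adjusted p = 0.12 with an estimated correlation) did not. The Poria count of 704 was 410 without vehicle replicate 1, 411 without Poria replicate 3 and 232 from the 6 libraries alone.

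Atractylodis at 500 µg/mL raised inflammatory genes. SAA2, an acute-phase serum amyloid (ENSG00000134339, chromosome 11, 18239223 to 18248643), rose from 10.7 ± 0.618 to 35.2 ± 2.06 CPM (n = 3), by 1.72 ± 0.076 (SE, adjusted p = 2.09e-26); it is near-identical to its neighbour SAA1, so reads of the pair are shared. The complement factor CFB rose from 5.57 ± 0.406 to 14.8 ± 1.68 CPM (4.91e-18), and the iron-binding LCN2 from 17.2 ± 0.581 to 34.6 ± 4.17 CPM (7.35e-15). The neutrophil chemokine CXCL1 rose from 18.9 ± 1.55 to 35.3 ± 4.06 CPM (8.26e-12) and the elastase inhibitor PI3 by 0.81. The T-cell chemokine CCL5 (ENSG00000271503, chromosome 17, 35871491 to 35880793) rose by 2.84 ± 0.267 and CXCL8 by 1.95 ± 0.168 in edgeR, at 3.88 ± 0.947 and 5.81 ± 0.205 CPM. DESeq2 called neither, and whether it gave these low-count genes an adjusted p was not separated.

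Of 25 NF-kB and cytokine genes 10 rose with Atractylodis at 500 µg/mL, or 15 adjusted over the list alone (median 0.36, list adjusted p = 1.4e-53, or 6.5e-13 with an estimated correlation). At 100 µg/mL 8 rose (median 0.34, 9e-45) and at 20 µg/mL 8 rose (median 0.20, 1.1e-18); SAA2 stood at 34.4 ± 1.75 and 28.3 ± 0.86 CPM at those doses. No other list kept a call at 500 µg/mL with an estimated correlation. The Atractylodis count of 81 was 48, 43 and 241 without vehicle replicates 1, 2 and 3, 196, 35 and 34 without its own replicates 1, 2 and 3, and 24 from the 6 libraries alone. It was 422 without a filter on low counts, 158 by DESeq2 and 159 with the replicate number as a block (161 with that block within each set of sample codes).

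Glycyrrhizae at 500 µg/mL raised the enzymes that the aryl hydrocarbon receptor induces. CYP1A1, a cytochrome P450 that oxidises aromatic compounds (ENSG00000140465, chromosome 15, 74719542 to 74725610), rose from 0.427 ± 0.317 to 46.4 ± 2.37 CPM (n = 3), by 6.72 ± 0.191 (SE, adjusted p = 4.09e-37). CYP1B1 rose from 115 ± 2.26 to 373 ± 20.1 CPM, the aldehyde dehydrogenase ALDH3A1 from 1130 ± 60.4 to 2561 ± 79.8 CPM, and AHRR, the repressor of the receptor, by 1.59. The water and glycerol channel AQP3 rose from 59.6 ± 2.69 to 142 ± 3.46 CPM (3.13e-35). The orphan nuclear receptor NR4A1 (ENSG00000123358, chromosome 12, 52022832 to 52059507) fell by 1.53 ± 0.094, from 18.4 ± 1.41 to 6.39 ± 0.586 CPM (3.23e-20); the atypical MAP kinase MAPK4, the tight junction gene CLDN2 and the Nodal inhibitor LEFTY1 fell by 1.47, 1.41 and 1.21.

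All 6 tested aryl hydrocarbon receptor targets rose with Glycyrrhizae at 500 µg/mL (median 1.39, list adjusted p = 3.3e-149, or 6.7e-26 with an estimated correlation), UGT1A6 among them although it shares its 3' exons with other UGT1A genes. Of 27 NRF2 targets 15 rose (median 0.17, 6.2e-14), with the cystine transporter SLC7A11 at 0.54 and the glutathione-synthesis enzyme GCLC at 0.34. Of 30 ATF4 genes 12 rose and 1 fell (8.9e-07), with ASNS at 0.48, and 19 of 25 G2/M genes rose (median 0.22, 5.6e-21), with TOP2A at 0.40. The p53 list was also called (2 of 22 higher, 0.018, or 0.029 with an estimated correlation). Calls lost with an estimated correlation were G1/S (7 of 26 higher, adjusted p = 0.067 with an estimated correlation), heat shock (4 of 17 higher, 0.31), lysosome (6 of 30 lower, 0.31) and metallothioneins (1 of 5 lower, 0.14). The NF-kB list was not called, with 3 of 25 members higher and 5 lower; SAA2 rose by 0.86 and NFKB2, an NF-kB precursor, fell by 0.65. The Glycyrrhizae count of 1716 was 1123 without its replicate 2 and 786 from the 6 libraries alone. Residuals of equal replicate numbers correlated positively here (lowest of 3 correlations 0.2), and the blocked count was 1892.

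Panax at 500 µg/mL gave small changes. ID3, like ID2 an inhibitor of helix-loop-helix factors (ENSG00000117318, chromosome 1, 23557918 to 23559794), fell by 0.33 ± 0.053 (SE), from 160 ± 9.92 to 128 ± 5.35 CPM (n = 3, adjusted p = 0.00167), and this call was lost without vehicle replicate 2 (adjusted p = 0.0744). The FOXO list moved up (1 of 22 members higher, or 7 adjusted over the list alone; median 0.09, list adjusted p = 0.00013, or 0.028 with an estimated correlation). No G1/S gene was called; 7 of 26 were lower adjusted over the list alone (adjusted p = 0.14 with an estimated correlation), as were 9 of 22 ribosome biogenesis genes (adjusted p = 0.14 with an estimated correlation). The Panax count of 105 was 36, 3 and 367 without vehicle replicates 1, 2 and 3, and 177, 9 and 8 without its own replicates 1, 2 and 3. It was 7 from the 6 libraries alone, 455 without a filter, 275 by DESeq2 and 255 with a replicate block (301 within sets).

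Angelicae at 500 µg/mL lowered both ID genes and raised a pair of aryl hydrocarbon receptor targets. ID3 fell by 0.44 ± 0.053 (SE), to 118 ± 5.3 CPM (n = 3, adjusted p = 7e-07), and ID2 fell by 0.58 ± 0.074, to 17.8 ± 0.823 CPM (1.16e-06). AQP3 rose by 0.30, to 73.6 ± 2.77 CPM (1.48e-06), and CYP1B1 by 0.29, from 115 ± 2.26 to 141 ± 7.56 CPM (0.000406). The aryl hydrocarbon receptor list was higher, with 2 of 6 members called (median 0.27, list adjusted p = 5.2e-08, or 7.7e-06 with an estimated correlation). NRF2 targets had 1 of 27 members higher, or 9 adjusted over the list alone (adjusted p = 0.088 with an estimated correlation), and G2/M genes were called only with the preset correlation (adjusted p = 0.059 with an estimated correlation). The Angelicae count of 33 was 13, 14 and 168 without vehicle replicates 1, 2 and 3, and 15 and 11 without its own replicates 2 and 3. It was 12 from the 6 libraries alone, 295 without a filter, 133 by DESeq2 and 126 with a replicate block (150 within sets).

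Paeoniae at 500 µg/mL raised the genes that low oxygen induces and lowered NF-kB targets and both ID genes. ALDOC, a glycolytic aldolase (ENSG00000109107, chromosome 17, 28573115 to 28577264), rose from 13.0 ± 1.21 to 33.1 ± 1.91 CPM (n = 3), by 1.34 ± 0.103 (SE, adjusted p = 4.4e-14). NDRG1, a stress-induced growth regulator, rose from 104 ± 5.35 to 184 ± 6.02 CPM (2.29e-20), the collagen prolyl hydroxylase P4HA1 from 32.4 ± 1.04 to 56.8 ± 4.85 CPM (1.55e-15), and MIR210HG, the host gene of a hypoxia-induced microRNA, from 3.86 ± 0.457 to 9.50 ± 0.447 CPM. ID3 fell by 0.98 ± 0.055, from 160 ± 9.92 to 81.2 ± 7.45 CPM (2.29e-20), and ID2 fell by 1.18 ± 0.079, to 11.7 ± 1.34 CPM (6.51e-18). The monocyte chemokine CCL2 fell by 1.00 and the NF-kB subunit RELB by 0.80 on the log2 scale. The antisense gene PDK1-AS1 was called at 1.44 in edgeR and not in DESeq2; it lies antisense at the PDK1 locus, so the origin of its reads is uncertain.

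Of 24 hypoxia and glycolysis genes 22 rose with Paeoniae at 500 µg/mL, or 23 adjusted over the list alone (median 0.54, list adjusted p = 3.2e-92, or 5.4e-12 with an estimated correlation). PDK1, which diverts pyruvate from the mitochondria, and CA9, a carbonic anhydrase, both chosen after their values were seen, rose by 0.92 and 0.86. Of 25 NF-kB genes 11 fell (median -0.28, 6.9e-10), NFKB2 by a log2 change of -0.56, and 14 of 22 ribosome biogenesis genes fell (median -0.17, 2.3e-14), with NOP16 at -0.31. Of 22 FOXO-activated genes 12 rose (median 0.20, 2.6e-10), with ERBB3 at 0.36 and CCNG2 at 0.46. Of 6 aryl hydrocarbon receptor targets 5 rose (median 0.47, 3.2e-12), ALDH3A1 by 0.46, and 7 of 22 p53 targets rose (3.1e-06), DDB2 by 0.26. Of 13 glucocorticoid receptor targets 4 rose (0.00034), with ANGPTL4 at 0.66, and 2 of 5 metallothionein and zinc export genes fell (0.0021, or 0.047 with an estimated correlation). Heat shock genes had 8 of 17 members lower (adjusted p = 0.058 with an estimated correlation) and fatty acid genes 4 of 12 higher (adjusted p = 0.13 with an estimated correlation). The Paeoniae count of 1640 was 886 without vehicle replicate 2, 993 and 894 without its own replicates 2 and 3, and 640 from the 6 libraries alone.

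**Figure D2:**
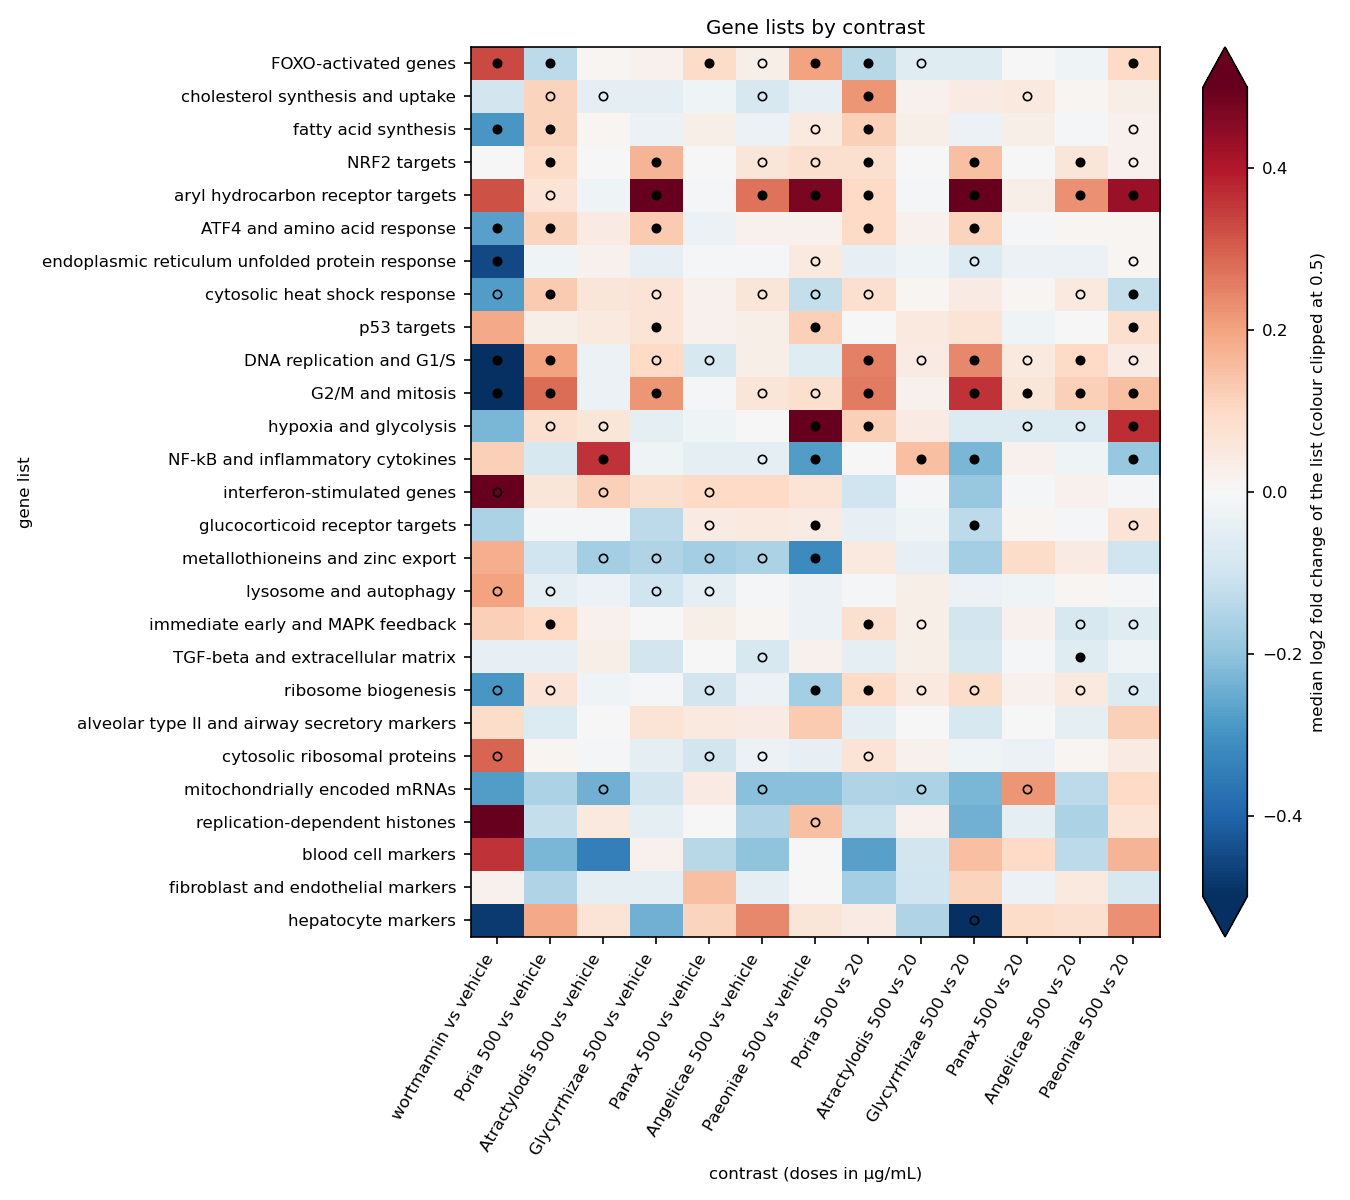
Each cell gives the median log2 change of a gene list (27 lists, down the side) in a comparison (13, along the bottom), with colour clipped at 0.5 in both directions; an open circle marks a camera adjusted p under 0.05 and a filled circle a call that holds with an estimated correlation. Wortmannin lowered both cell cycle lists (medians -2.81 and -1.36), and Glycyrrhizae, Paeoniae and Atractylodis at 500 µg/mL each had their highest median in another list (1.39 for aryl hydrocarbon receptor targets, 0.54 for hypoxia, 0.36 for NF-kB).

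At 100 µg/mL rises and falls were 130 and 126 with Poria, 52 and 26 with Atractylodis, 48 and 41 with Glycyrrhizae, 31 and 13 with Panax, 29 and 25 with Angelicae, and 86 and 59 with Paeoniae. At 20 µg/mL they were 3 and 3, 51 and 39, 102 and 75, 221 and 175, 26 and 12, and 258 and 191 in that order. Paeoniae at 100 µg/mL raised 7 of 24 hypoxia genes, or 16 adjusted over the list alone (median 0.22, list adjusted p = 5.4e-18, or 0.00082 with an estimated correlation). Glycyrrhizae at 100 µg/mL raised 2 of 6 aryl hydrocarbon receptor targets (median 0.43, 5e-19, or 2.7e-10 with an estimated correlation), CYP1B1 to 157 ± 11.7 CPM and ALDH3A1 to 1565 ± 45.8 CPM, while CYP1A1 stood at 0.962 ± 0.207 CPM and was not called. Residuals of equal replicate numbers correlated positively between Glycyrrhizae at 100 µg/mL and vehicle (lowest of 3 correlations 0.133). The Glycyrrhizae count of 89 was 208 with the replicate number as a block. Poria at 100 µg/mL raised 6 of 25 G2/M genes, or 16 adjusted over the list alone (median 0.14, 1e-15). At 20 µg/mL 7 of 26 G1/S genes fell with Panax (adjusted p = 0.0022 with an estimated correlation). With Glycyrrhizae 6 fell (median -0.15, 1.4e-05 with an estimated correlation) and with Paeoniae 4 (median -0.12, adjusted p = 0.014 with an estimated correlation). Compared directly at 20 µg/mL, the list was not called between Glycyrrhizae and Panax (median -0.026, adjusted p = 0.51 with an estimated correlation). No pair of extracts differed at that dose in more than 31 genes (Poria and Glycyrrhizae). These falls may thus be a difference from vehicle that the extracts share.

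These low-dose counts moved by over 1.5 times without single vehicle libraries. Without vehicle replicate 3 the counts at 100 µg/mL were 565 with Poria, 282 with Atractylodis, 164 with Glycyrrhizae, 305 with Panax, 483 with Angelicae and 542 with Paeoniae. At 20 µg/mL, without that library, they were 82 with Poria, 403 with Atractylodis, 787 with Panax, 206 with Angelicae and 933 with Paeoniae. Without vehicle replicate 1 those at 100 µg/mL were 19, 23, 51, 2, 4 and 15 in the order Poria, Atractylodis, Glycyrrhizae, Panax, Angelicae and Paeoniae. At 20 µg/mL they were 1 with Poria, 13 with Atractylodis, 141 with Panax, 4 with Angelicae and 122 with Paeoniae. Without vehicle replicate 2 those at 100 µg/mL were 146 with Poria, 49 with Glycyrrhizae, 7 with Panax, 6 with Angelicae and 39 with Paeoniae, and at 20 µg/mL 1, 34, 48, 62, 5 and 26 in the order given. Extract libraries moved them as well. Without replicate 1 the counts were 177 (Atractylodis, 20), 74 (Panax, 100), 2 and 18 (Angelicae, 100 and 20), and 56 and 295 (Paeoniae, 100 and 20). Without replicate 2 they were 71 and 2 (Poria, 100 and 20), 41 and 10 (Atractylodis), 35 and 79 (Glycyrrhizae), 3 and 98 (Panax), 493 and 4 (Angelicae), and 64 (Paeoniae, 100). Without replicate 3 they were 28 and 0 (Poria, 100 and 20), 26 and 14 (Atractylodis), 43 and 33 (Glycyrrhizae), 3 and 58 (Panax), 1 and 15 (Angelicae), and 36 and 73 (Paeoniae). Of the other settings, Panax at 20 µg/mL gave 66 calls from the 6 libraries alone, 658 without a filter, 655 by DESeq2 and 254 with GC and length offsets.

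**Figure D3:**
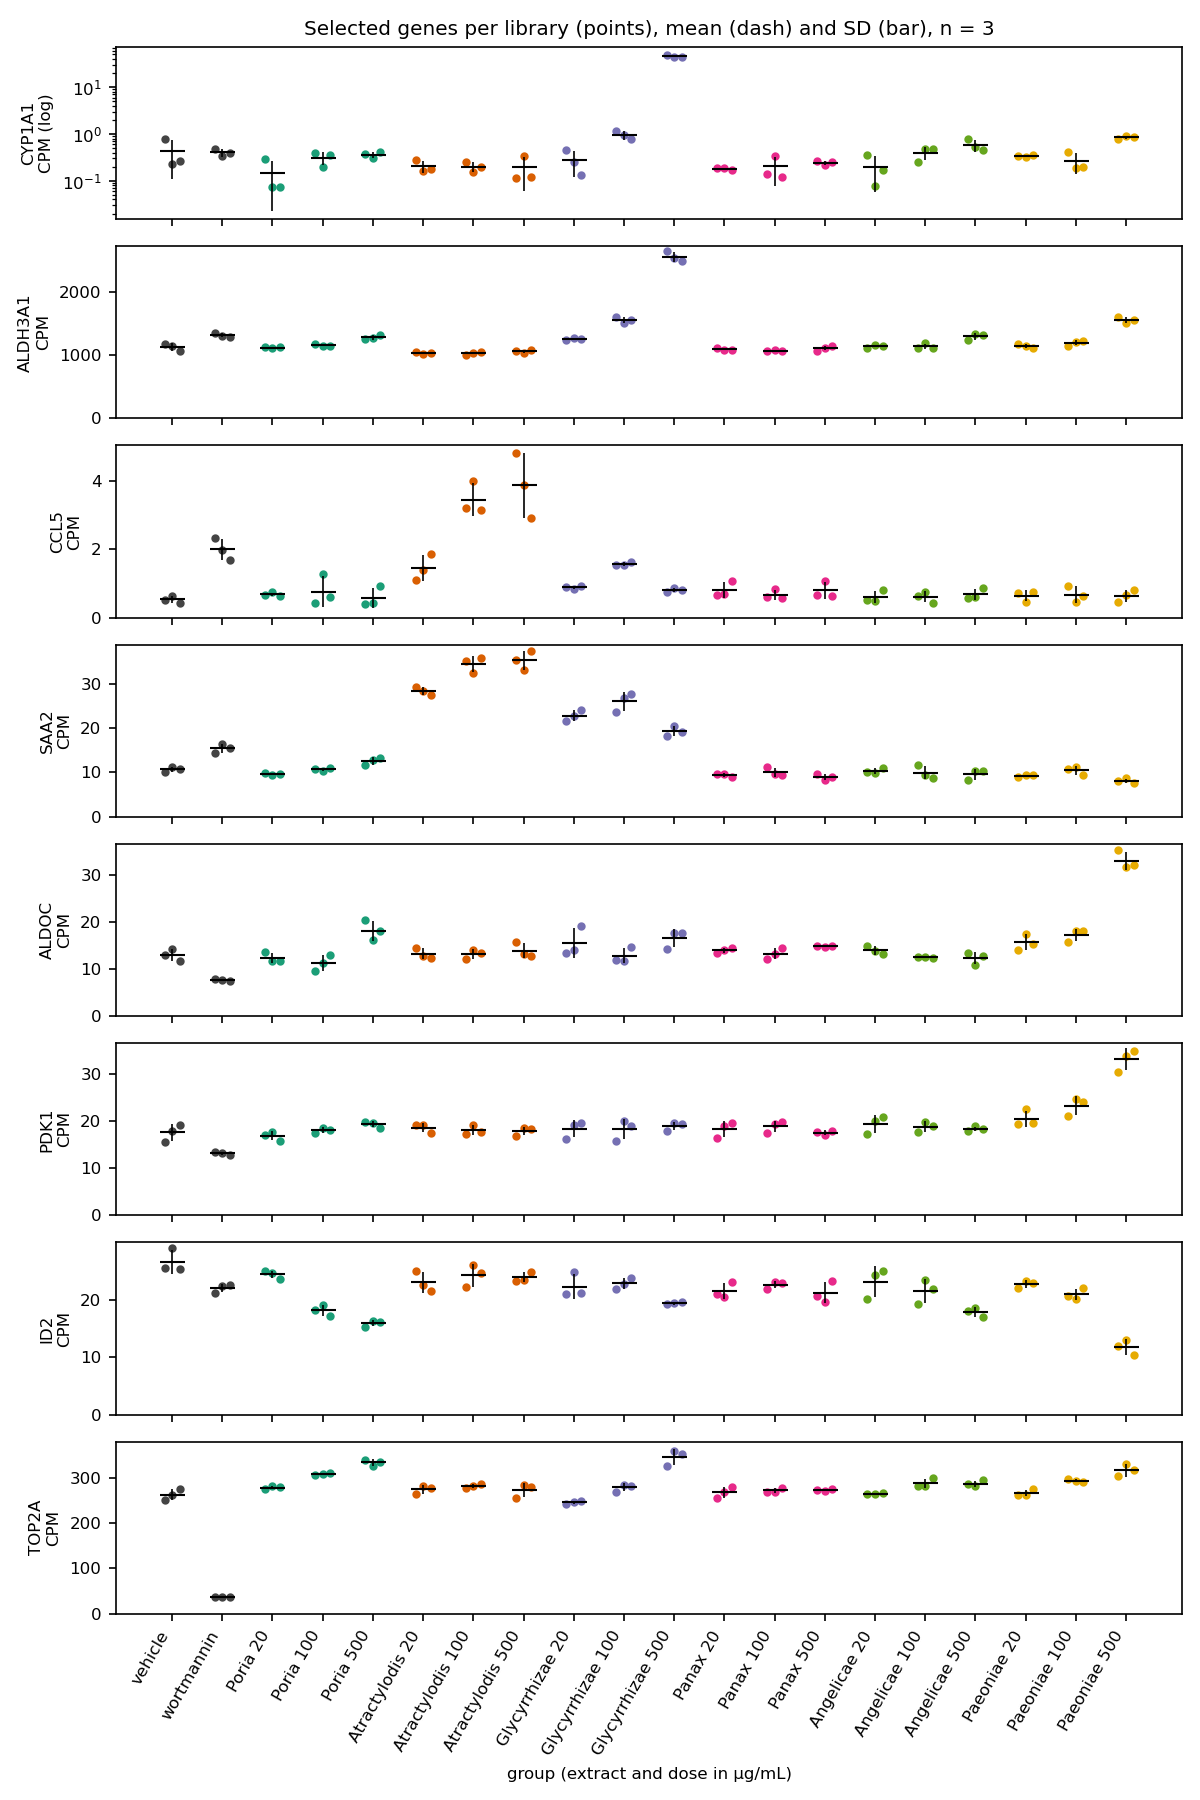
Points give the CPM of 8 genes in each library (CYP1A1 on a log axis, the others linear) for vehicle, wortmannin and the 6 extracts by dose, with a dash at the mean and a bar of 1 SD over 3 libraries. CYP1A1 reaches 46.4 ± 2.37 CPM with Glycyrrhizae at 500 µg/mL against 0.427 ± 0.317 in vehicle, SAA2 is above vehicle at all Atractylodis doses (35.2, 34.4 and 28.3 against 10.7 CPM), and ALDOC reaches 33.1 ± 1.91 CPM with Paeoniae at 500 µg/mL.

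Comparing 500 with 20 µg/mL of the same extract asked which changes depended on dose, within 1 set of sample codes and without the vehicle libraries. With Glycyrrhizae 984 genes were higher and 1200 lower at 500 than at 20 µg/mL. CYP1A1 differed by 7.33 ± 0.207 (SE, n = 3, adjusted p = 3.89e-37) and all 6 aryl hydrocarbon receptor targets were higher (median 1.21, list adjusted p = 4.2e-118). All 25 G2/M genes were higher (median 0.36, 2.2e-45), as were 21 of 26 G1/S genes (2.4e-23) and 15 of 27 NRF2 targets, against 1 lower (7.7e-12). Of 25 NF-kB genes 11 were lower and 1 higher (median -0.23, 9.8e-06), with NFKB2 at 34.8 ± 0.524 against 52.4 ± 2.0 CPM, and 6 of 13 glucocorticoid targets were lower and 1 higher (0.0019, or 0.043 with an estimated correlation). CLDN2 fell by 1.93, from 6.43 ± 0.492 to 1.70 ± 0.368 CPM. The unfolded protein response list was called only with the preset correlation (5 of 21 lower, adjusted p = 0.095 with an estimated correlation).

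With Poria 372 genes were higher and 191 lower at 500 than at 20 µg/mL. Of 25 cholesterol genes 10 were higher, or 18 adjusted over the list alone (median 0.22, list adjusted p = 1.2e-20, or 0.0065 with an estimated correlation); FDPS, an isoprenoid synthase, stood at 156 ± 2.63 against 124 ± 1.35 CPM. Higher too were 21 of 26 G1/S genes (median 0.25, 1.1e-42), 19 of 25 G2/M genes (median 0.26, 1.7e-45), 7 of 30 ATF4 genes (7.9e-09) and 5 of 24 hypoxia genes (3.8e-10), and 4 of 22 FOXO-activated genes were lower (4.1e-08). ADH6, an alcohol dehydrogenase, and ANGPT4, an angiopoietin, fell by 0.80 and 0.74 in edgeR, which DESeq2 did not call. The Poria count of 563 was 373 and 359 without the 500 µg/mL replicates 1 and 3 and 326 without the 20 µg/mL replicate 3. Residuals of equal replicate numbers correlated positively here (lowest correlation 0.137), and the blocked count was 729.

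With Paeoniae 206 genes were higher and 179 lower at 500 than at 20 µg/mL. Of 24 hypoxia genes 22 were higher (median 0.37, list adjusted p = 6.1e-108), with ALDOC at 33.1 ± 1.91 against 15.7 ± 1.72 CPM and the hexokinase HK2 higher by 0.81. Aryl hydrocarbon receptor targets (4 of 6 higher, 8.6e-15), p53 targets (3 of 22 higher, 2.3e-05) and G2/M genes (5 of 25 higher, 2.8e-13) were higher, and NF-kB genes (4 of 25 lower, 2.7e-09) and heat shock genes (3 of 17 lower, 2.7e-09) were lower. ID2 fell by 0.96, from 22.7 ± 0.627 to 11.7 ± 1.34 CPM, and the transcriptional coregulator gene ANKRD1 fell by 0.89. The Paeoniae count of 385 was 219 without the 20 µg/mL replicate 1 and 237 from the 6 libraries alone.

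With Angelicae CYP1B1 was higher by 0.32 (adjusted p = 0.000297), ALDH3A1 was higher by 0.18 and ID2 lower by a log2 change of -0.38 (both 0.0366) at 500 than at 20 µg/mL, 3 genes in all. The G2/M list was higher (no gene called, 15 of 25 adjusted over the list alone; median 0.12, list adjusted p = 3.7e-26, or 1.5e-08 with an estimated correlation), as were G1/S genes (8 of 26 adjusted over the list alone, 2.4e-15), aryl hydrocarbon receptor targets (2 of 6 called, median 0.23, 2.4e-14) and NRF2 targets (4 of 27 adjusted over the list alone, 6.5e-09); TGF-beta genes were lower (3 of 21 adjusted over the list alone, 7.1e-05). The count of 3 was 1 without the 500 µg/mL replicate 2 or 3 and 0 without the 20 µg/mL replicate 2. ALDH3A1 was also not called without the 20 µg/mL replicate 1 or 3 (adjusted p = 0.237 and 0.166), nor ID2 without the 500 µg/mL replicate 1 or the 20 µg/mL replicate 3 (0.0998 and 0.282). The count was 1 from the 6 libraries alone, 64 without a filter, 21 by DESeq2, 11 with a replicate block and 8 with GC and length offsets. Another split of the 6 libraries called 19 genes. The lists were not tested over such splits, so differences between libraries apart from dose may contribute to the list calls.

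With Atractylodis CCL5 was higher by 1.39 (adjusted p = 0.000567) and PI3 by 0.43 at 500 than at 20 µg/mL, and no other gene was called. The count of 2 was 1 without replicate 1 of either dose, in each case without CCL5 (adjusted p = 0.075 and 0.0564 without replicate 1 at 500 and at 20 µg/mL), and 7 without the 500 µg/mL replicate 2; it was 4 from the 6 libraries alone, 80 without a filter and 5 with a replicate block within sets. The NF-kB list was higher (no gene called, 4 of 25 adjusted over the list alone; median 0.15, list adjusted p = 3.7e-14, or 1.9e-05 with an estimated correlation). With Panax edgeR called 0 genes between 500 and 20 µg/mL, against 879 at an unadjusted p under 0.05 and 1 by DESeq2 (88 without a filter, 1 from the 6 libraries alone). The G2/M list differed by a median of 0.06 (list adjusted p = 2.3e-06, or 0.01 with an estimated correlation). Another split of the 6 libraries called 94 genes for Atractylodis (4 in the real one) and 47 for Panax (1 in the real one). The lists were not tested over such splits, so differences between libraries apart from dose may contribute to the list calls of both extracts.

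Extracts of the same set of sample codes were compared directly at 500 µg/mL, which asked where their effects differed without the vehicle libraries. Between Poria and Atractylodis 330 genes were higher and 215 lower with Poria. HMOX1 was higher by 0.72 (n = 3, adjusted p = 3.82e-07), SAA2 lower by a log2 change of -1.48 (7.94e-24) and CFB by -1.40; 22 of 25 G2/M and 21 of 26 G1/S genes were higher and 14 of 25 NF-kB genes lower (median -0.48, adjusted p = 9.6e-13 with an estimated correlation). The count of 545 was 350 without Poria replicate 3 and 329 from the 6 libraries alone.

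Between Glycyrrhizae and Panax 772 genes were higher and 1035 lower with Glycyrrhizae. CYP1A1 differed by 7.55 (n = 3, adjusted p = 1.02e-37), NR4A1 by -1.55 and CLDN2 by -1.88. All 6 aryl hydrocarbon receptor targets, 21 of 25 G2/M genes, 15 of 26 G1/S genes, 12 of 30 ATF4 genes (1 lower) and 18 of 27 NRF2 targets (1 lower) were higher, each list called with an estimated correlation too. The count of 1807 was 1151 without Panax replicate 3.

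Between Angelicae and Paeoniae 257 genes were higher and 267 lower with Angelicae. ALDOC was lower by a log2 change of -1.41 (n = 3, adjusted p = 1.22e-14), MIR210HG by -1.36, and CCL2 higher by 0.78. Of 24 hypoxia genes 22 were lower with Angelicae (median -0.48, 3.4e-145, or 3.4e-15 with an estimated correlation); 9 of 17 heat shock genes, 8 of 22 ribosome biogenesis genes and 4 of 25 NF-kB genes were higher, and 4 of 22 p53 targets lower, all called with an estimated correlation as well. The count of 524 was 335 without Angelicae replicate 2 and 294 without Paeoniae replicate 3.

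The dose responses of the extracts (500 against 20 µg/mL) were compared with each other across genes, which are not independent replicates. Over 15 pairs the median Pearson correlation was -0.007 over all tested genes and 0.072 over the 9359 genes with a mean of at least 10 CPM, where it was 0.423 for Poria and Glycyrrhizae, 0.406 for Glycyrrhizae and Angelicae, 0.364 for Poria and Angelicae and 0.352 for Poria and Atractylodis. Over all tested genes these 4 pairs gave Pearson correlations of 0.081, 0.077, -0.025 and 0.145 and Spearman correlations of 0.214, 0.221, 0.139 and 0.172, in that order. These Pearson correlations moved widely with a replicate number left out. Without numbers 1, 2 and 3 they were 0.019, 0.141 and 0.005 for the first pair, 0.086, 0.01 and 0.054 for the second, -0.087, 0.063 and 0.006 for the third and 0.126, 0.046 and 0.153 for the fourth. Poria and Glycyrrhizae shared 233 genes higher and 99 lower at the higher dose, where 21.5 and 13.5 would be shared if the calls were independent. Glycyrrhizae and Paeoniae shared 74 higher and 99 lower (11.9 and 12.6 if independent).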

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

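The tests of Atractylodis and NF-kB genes, the vehicle and GC tests of Paeoniae and hypoxia genes, and the GC and length offsets were chosen after the result was seen; the others were not.

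The change from 20 to 500 µg/mL differed between the extracts of a pair, tested as an interaction in edgeR, in 34 genes between Poria and Atractylodis (24 with the higher change with Poria, 10 with the lower). It differed in 781 genes between Glycyrrhizae and Panax (281 higher, 500 lower) and in 108 genes between Angelicae and Paeoniae (36 higher, 72 lower). In the list test of the same difference, aryl hydrocarbon receptor targets changed more with Glycyrrhizae than with Panax (median 1.09, adjusted p = 2.5e-18 with an estimated correlation), and hypoxia genes less with Angelicae than with Paeoniae (median -0.46, 5.8e-12). G2/M genes changed more with Poria than with Atractylodis (median 0.24, 7.8e-10).

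Panax gave 396 called genes at 20 µg/mL against vehicle but 0 between 500 and 20 µg/mL by edgeR (879 at an unadjusted p under 0.05, 1 by DESeq2). A difference between the vehicle libraries and all extract libraries may account for much of this: Panax at 20 µg/mL differed from the other 5 extracts at that dose in a median of 3 genes. That test could not separate such a difference from an effect shared by any plant extract. A single vehicle library stays open, since the count was 62 without vehicle replicate 2, 141 without replicate 1 and 787 without replicate 3. GC content and gene length also stay open, with 49.7% of the called genes still called after the offsets. Paeoniae at 20 µg/mL had 449 called genes against vehicle. At that dose it differed in 0 genes from Panax and from Angelicae, 3 from Poria, 7 from Glycyrrhizae and 16 from Atractylodis. A difference of the vehicle libraries may therefore account for part of its count too, though no rule was set for this comparison.

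NF-kB and cytokine genes were higher with Atractylodis at all 3 doses. A difference of the vehicle libraries from all extracts is argued against as the whole cause, since the list was also higher with Atractylodis than with Poria at 20 µg/mL (median 0.2, adjusted p = 3.1e-12 with an estimated correlation). GC content and gene length as the whole cause are argued against by a median of 0.38 at 500 µg/mL with the offsets, against 0.36 without them. An effect of the extract preparation on these genes is a hypothesis left. Differences in the culture or handling of these libraries were not tested. The data cannot say whether an effect of the preparation came from a plant compound or from another component such as bacterial products, which was not tested.

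Hypoxia and glycolysis genes were higher with Paeoniae at 500 µg/mL. The vehicle libraries as the whole cause are argued against by the same list being higher at 500 than at 20 µg/mL (median 0.37). GC content and gene length are argued against by a median of 0.54 with the offsets, and a single Paeoniae library by 21 of 24 members still called with any of the 3 left out. An effect of the extract may then be the explanation, as a hypothesis found and tested on the same data; whether cell density or oxygen in the wells differed was not recorded in the labels.

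For each contrast the 6 libraries allow 10 splits into 3 and 3, which cannot give a share under 0.05. The number of splits with as many calls was 1 for wortmannin (7737 calls, highest other split 0). At 500 µg/mL against vehicle it was 1 for Poria (232, other 4), 2 for Atractylodis (24, other 34), 1 for Glycyrrhizae (786, other 1), 1 for Panax (7, other 6), 1 for Angelicae (12, other 3) and 1 for Paeoniae (640, other 2). At 100 µg/mL it was 1 for Poria (36, other 6), 1 for Atractylodis (49, other 3), 1 for Glycyrrhizae (37, other 23), 2 for Panax (12, other 49), 10 for Angelicae (0, other 30) and 1 for Paeoniae (11, other 4). At 20 µg/mL it was 10 for Poria (0, other 5), 1 for Atractylodis (20, other 4), 2 for Glycyrrhizae (33, other 33), 1 for Panax (66, other 1), 4 for Angelicae (2, other 10) and 1 for Paeoniae (83, other 2). Between 500 and 20 µg/mL it was 1 for Poria (602, other 4), 4 for Atractylodis (4, other 94), 1 for Glycyrrhizae (1468, other 2), 7 for Panax (1, other 47), 6 for Angelicae (1, other 19) and 1 for Paeoniae (237, other 14). Between extracts it was 1 for Poria and Atractylodis (329, other 3), 1 for Glycyrrhizae and Panax (1376, other 12) and 1 for Angelicae and Paeoniae (378, other 6). Other splits called several times the real count for Panax at 100 µg/mL, Angelicae at 20 µg/mL, and Atractylodis, Panax and Angelicae between doses. For Angelicae at 100 µg/mL another split called 30 genes and the real one 0. Differences between libraries that the groups do not describe may underlie this, which was not tested. These fits used the 6 libraries only, so their real counts differ from those of the fit to all 60.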

How the results depend on the processing

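The GC and length offsets and the fit without the 6 libraries apart on the second principal component were added after the data were seen; the other alternatives were planned. The wortmannin count stayed within 1.5 times of the reported value under every alternative run, and 99 of 168 counts with a library left out moved beyond that range. Of 493 results for named genes 235 kept direction and call under all alternatives; the weaker ones numbered 178 with the 6 libraries only, 138 without the 6 libraries apart, 105 by DESeq2, 62 with GC and length offsets, 27 without a filter and 13 with RLE size factors. Those by DESeq2 include genes that it left without an adjusted p. Over all left-out libraries and named genes, 2252 refits kept the call and 706 were weaker. Of 351 list tests 129 were called, and 62 with an estimated correlation. With fry 26 list calls were lost and 34 gained, and uncalled lists whose sign changed without a call, 161 in all, were counted as unchanged. Cytosolic ribosomal proteins with Angelicae at 500 µg/mL against vehicle reversed direction without vehicle replicate 2, with an adjusted p of 0.9; the other left-out libraries gave adjusted p down to 6e-05. Apart from the smaller number of samples in some settings, the cause was not tested.

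With the 6 libraries only, where fewer samples estimate the spread, counts against vehicle were 232, 36 and 0 for Poria at 500, 100 and 20 µg/mL, 24, 49 and 20 for Atractylodis, 786, 37 and 33 for Glycyrrhizae, 7, 12 and 66 for Panax, 12, 0 and 2 for Angelicae, and 640, 11 and 83 for Paeoniae. Between 500 and 20 µg/mL they were 4 for Atractylodis, 1 for Panax, 1 for Angelicae and 237 for Paeoniae, and 329 between Poria and Atractylodis.

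Without a filter on low counts they were 619 and 162 for Poria at 100 and 20 µg/mL, 422, 425 and 371 for Atractylodis at 500, 100 and 20 µg/mL, 257 and 355 for Glycyrrhizae at 100 and 20 µg/mL, 455, 292 and 658 for Panax, 295, 458 and 264 for Angelicae, and 500 and 767 for Paeoniae at 100 and 20 µg/mL. Between doses they were 80 for Atractylodis, 88 for Panax and 64 for Angelicae. By DESeq2 they were 598 and 48 for Poria at 100 and 20 µg/mL, 158, 218 and 378 for Atractylodis, 181 and 319 for Glycyrrhizae at 100 and 20 µg/mL, 275, 170 and 655 for Panax, 133, 355 and 134 for Angelicae, 327 and 782 for Paeoniae at 100 and 20 µg/mL, and between doses 1 for Panax and 21 for Angelicae.

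With the replicate block they were 393 and 29 for Poria at 100 and 20 µg/mL, 159, 185 and 273 for Atractylodis, 208 and 334 for Glycyrrhizae at 100 and 20 µg/mL, 255, 166 and 624 for Panax, 126, 275 and 133 for Angelicae, 287 for Paeoniae at 100 µg/mL and 11 for Angelicae between doses. With the replicate block within each code set they were 411 and 54 for Poria, 161, 209 and 329 for Atractylodis, 238 and 367 for Glycyrrhizae, 301, 196 and 728 for Panax, 150, 294 and 162 for Angelicae, and 341 and 708 for Paeoniae, and between doses 5 for Atractylodis and 11 for Angelicae. All 3 correlations of equal numbers were above 0.1 only in Glycyrrhizae at 500 and 100 µg/mL against vehicle and in Poria between doses. Other contrasts had correlations as far below 0, such as -0.361 and -0.279 for Poria at 500 µg/mL against vehicle. A pairing of the samples by number is thus not shown.

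With GC and length offsets they were 99 for Poria at 100 µg/mL, 25 for Atractylodis at 20 µg/mL, 26 and 254 for Panax at 100 and 20 µg/mL, 16 for Angelicae at 100 µg/mL, 83 and 212 for Paeoniae at 100 and 20 µg/mL, and 8 for Angelicae between doses. With RLE size factors 90 genes were called for Angelicae at 100 µg/mL, against 54.

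Without the 6 libraries apart on the second principal component, against vehicle, they were 315, 24 and 1 for Poria at 500, 100 and 20 µg/mL, 25 and 20 for Atractylodis at 100 and 20 µg/mL, 1121 and 45 for Glycyrrhizae at 500 and 100 µg/mL, 65, 10 and 149 for Panax, 16, 6 and 6 for Angelicae, and 33 and 160 for Paeoniae at 100 and 20 µg/mL, and 1 for Atractylodis between doses. The other 12 counts stayed within 1.5 times, among them those of Paeoniae at 500 µg/mL (1275), of all 3 comparisons between extracts and of Glycyrrhizae between doses (1972). Of the 351 list tests 134 were called.

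With 1 library left out, the lowest and highest counts were 7253 and 7636 for wortmannin. For 500, 100 and 20 µg/mL against vehicle they were 410 to 670, 19 to 565 and 0 to 82 for Poria, 34 to 241, 23 to 282 and 10 to 403 for Atractylodis, 1123 to 1748, 35 to 164 and 33 to 248 for Glycyrrhizae, 3 to 367, 2 to 305 and 58 to 787 for Panax, 11 to 168, 1 to 493 and 4 to 206 for Angelicae, and 886 to 1861, 15 to 542 and 26 to 933 for Paeoniae. Between doses they were 326 to 476 for Poria, 1 to 7 for Atractylodis, 1491 to 2018 for Glycyrrhizae, 0 to 0 for Panax, 0 to 2 for Angelicae and 219 to 296 for Paeoniae. Between extracts they were 350 to 468 for Poria and Atractylodis, 1151 to 1799 for Glycyrrhizae and Panax, and 294 to 542 for Angelicae and Paeoniae.

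The median correlation between dose responses (-0.007) was 0.072 over genes of at least 10 CPM, between 0.005 and 0.02 with a replicate number left out, and 0.493 for 500 µg/mL against vehicle. Groups simulated without a change gave 0.507 against simulated vehicle libraries that they shared (0.443 to 0.56). A median correlation of that size can thus come from a shared vehicle alone. The median covariance over pairs was 0.0621 for the real extracts, against 0.0544 in the simulations (0.0437 to 0.0608 over 20 draws). By covariance a shared vehicle alone thus gave less than the real extracts showed. Genes were drawn independently there, so what makes up the excess was not separated. The highest real pair, Panax and Angelicae, had a correlation of 0.607, against a highest of 0.604 in the simulations. In counts simulated at this depth, spread and number of libraries, 26 of the 50 genes given the smallest change were called, so an uncalled gene is not shown to be unchanged. Depth was not varied, so its share in this limit was not separated from that of the spread between libraries.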

Other observations

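NF-kB and cytokine genes were also higher than vehicle with Glycyrrhizae at its lower doses. Of 25 tested, 5 rose and 1 fell at 100 µg/mL (median 0.16, adjusted p = 4e-07 with an estimated correlation). SAA2 stood at 19.4, 26.0 and 22.8 CPM at 500, 100 and 20 µg/mL against 10.7 CPM in vehicle, and CFB at 7.73, 11.1 and 10.9 CPM against 5.57 CPM. CXCL8 stood at 2.09, 3.64 and 3.33 CPM against 1.51 CPM; edgeR called it at 100 and 20 µg/mL and DESeq2 did not. At 20 µg/mL 6 of the 25 rose (median 0.13, adjusted p = 1.5e-05 with an estimated correlation), and 6 were higher with Glycyrrhizae than with Panax at that dose (adjusted p = 2e-09 with an estimated correlation). The 3 named genes were chosen after their values were seen, and no explanation was tested.

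ID2, ID3 and SMAD6, which BMP signalling induces, stood lower than vehicle with all 6 extracts at 500 µg/mL, though not all were called. ID2 was at 11.7 CPM with Paeoniae, 15.9 with Poria, 17.8 with Angelicae, 19.4 with Glycyrrhizae, 21.2 with Panax and 23.9 with Atractylodis, against 26.6 in vehicle. ID3 was at 81.2, 121, 118, 112, 128 and 149 CPM in the same order, against 160, and SMAD6 at 11.9, 12.6, 13.4, 14.2, 14.7 and 15.7 CPM, against 17.2. With Atractylodis none of the 3 genes was called. ID2 also stood below the vehicle mean with all 6 extracts at 20 µg/mL. It was at 22.7 CPM with Paeoniae and 23.1 CPM with Angelicae at that dose. The wortmannin libraries held 21.2, 22.4 and 22.5 CPM of ID2. The Panax libraries held 21.0, 20.4 and 23.0 CPM at 20 µg/mL and 20.7, 19.6 and 23.2 CPM at 500 µg/mL. Part of the ID2 difference from vehicle was thus not particular to the highest dose or to the extracts. SMAD6 was chosen after its values were seen, and the vehicle libraries are common to all these differences.

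NR4A1 stood at 6.47 ± 0.332 CPM with wortmannin and 6.39 ± 0.586 CPM with Glycyrrhizae at 500 µg/mL, against 18.4 ± 1.41 CPM in vehicle, and at 12.3 CPM with Glycyrrhizae at 100 µg/mL. The share of reads from mitochondrial genes lay between 13.4 and 19.7% over the 60 libraries. The first 2 principal components held 13.7 and 4.5% of the variance, and wortmannin lay apart from the other groups on the first. On the second 6 libraries lay apart: vehicle replicate 1 (-18.76), replicate 1 of Glycyrrhizae at 500, 100 and 20 µg/mL (-16.98, -20.85 and -18.22), Poria replicate 2 (-19.99) and Atractylodis replicate 1 (-13.28), both at 500 µg/mL. All others lay between -9.39 and 11.87. Between the Glycyrrhizae libraries at 500 µg/mL the squared difference per gene, relative to counting noise, was 23.08 for replicates 1 and 2, 15.63 for 1 and 3 and 2.97 for 2 and 3. Other groups reached such values too. Angelicae had 25.4 for replicates 2 and 3 at 100 µg/mL and 25.26 for replicates 1 and 3 at 20 µg/mL. The cause was not tested.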
